A study of Caenorhabditis elegans with 3 samples.

How the data were processed

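RNA of late third-stage (late L3) hermaphrodites of the nematode Caenorhabditis elegans was hybridised on 2-colour microarrays against a common wild-type mixed reference, per the labels. There were 3 arrays, which carried preparations (preps) 1, 2 and 3 of the larvae, and the reference was on the other channel of every array. The labels give no further group, and no word on whether the preps came from separate cultures. The p-values of single genes therefore measure the spread between these 3 samples, which may be partly technical. Each prep had its own array, with its own date in the array title, so prep, array and date are a single factor. The labels do not say which step the date refers to.

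The values used were the deposited log2 ratios of the 2 channels in the value table of the series. The log base was read from the values: 2 raised to the value was a whole number of thousandths, within 0.01 of a thousandth, for 100% of the ratios under 0.3 on each array, against 4.56%, 4.62% and 3.32% with base e. How the authors normalized these log2 ratios, which spots they filtered, and the image software are not given in the sources used here. Spot intensities were not used here, so signal over background, dye bias and saturation could not be examined. The channel in the numerator and the dyes are not given either. Late L3 over reference is used throughout as the likely direction, because the sample descriptions name the larvae before the reference, although the channel numbers put the reference first.

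The table held 20000 probes. Preps 1, 2 and 3 had values for 19909, 19855 and 19875 of them, with medians of 0.06, -0.05 and -0.0014 on the log2 scale. Values were present on all arrays for 19772 probes and on none for 23. The probe table given with the series named 1 gene for 15655 probes, several for 198 and no gene for 4147. No gene was named from a probe with several. Names of the 1-gene probes were updated through the RefSeq gene table of assembly WBcel235, by gene ID for 15569 and by accession for 7, while 79 kept the older name. That table was also used for chromosomes and for which genes neighbour each other. No coordinates are given, since the build behind the probes is not given in the sources used here.

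Each array was centred on its median, probes of a gene were averaged, and genes with values on all 3 arrays were tested, 15143 in all. Of these, 415 had more than 1 probe, and the probes of 17 differed by over 1 log2 unit. The mean log2 ratio of each gene was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes, 2-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. This test leaves out the spread of the reference itself. The prior had 7.96 degrees of freedom and an SD of 0.397. Errors are SD over the 3 preps unless stated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

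Before the data were examined, 24 gene lists were fixed for tissues, germ cells, cuticle, growth, stress and signalling, together with the tests, the alternatives and the rule for named genes. Lists with at least 5 measured genes, 23 of them, were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 23. Beside this, camera with an estimated correlation and fry were run. With an estimated correlation camera takes the residual degrees of freedom of the arrays, 2 here, so it rarely passes after adjustment and a miss says little about a list. Members past the threshold are counted over all genes tested and again adjusted over the list alone. X-linked and autosomal genes were compared with Fisher's exact test, 2-sided. The genes named are the 8 with the largest positive and the 8 with the largest negative mean among genes past the threshold with 1 sign on all arrays and a symbol of letters and a number, up to 4 members of each list with the largest means past the threshold (where fewer than 2 passed, the 2 with the largest means), and the vitellogenins. Others are said to have been chosen after their values were seen. Some genes that the rule names are not reported here.

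The test was run on simulated data with 200 changed genes among the 15143. It recovered 6%, 22%, 98% and 100% of the genes changed by 0.5, 1, 2 and 3 log2 units, and 5 of its 118 calls were false. The simulation held far fewer changed genes than were called in the data, which makes its adjusted threshold stricter, so these shares do not carry over to the data. The number of arrays limits the precision. Alternatives covered the centring and scaling of arrays, quantile normalization, missing values, the handling of several probes per gene, genes with a large spread, robust and weighted fits, a test without shared spread, other thresholds, turned signs and leaving out each prep. A running median over 201 probes in the order of their identifiers was subtracted as an alternative chosen after seeing the data.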

Results

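Transcript levels in 3 preps of late L3 hermaphrodites were measured as log2 ratios against a wild-type mixed reference on 2-colour arrays. The larvae are late in the larval stage that precedes L4, when the gonad grows and the vulva is being specified, and the stages or sexes pooled in the reference are not given in the sources used here. Between 19855 and 19909 probes had a value per array, and 15143 genes had one on all 3. Array values carry no count depth, so the number of arrays limits the precision.

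The only comparison of the design asks which transcripts of late L3 larvae stood above or below the mixed reference. All directions are the likely ones, late L3 over reference, and are relative to the array median. The infection response gene irg-5 on chromosome V stood highest, with a mean log2 ratio of 5.53 ± 1.22 (SD, n = 3), 46.2-fold. The heme-responsive gene hrg-7 (V) followed at 4.05 ± 1.25, then irg-8 (V) at 4.02 ± 0.64 and acdh-1 (I), an acyl-CoA dehydrogenase of the propionate shunt, which was at 3.91, 3.93 and 4.17 in preps 1, 2 and 3. At the other end were the yolk protein gene vit-2 (X) at -5.63 ± 1.24, 49.7-fold lower, the small heat shock protein gene hsp-12.6 (IV) at -4.72 ± 0.62, and perm-2 (IV), needed for the eggshell barrier, at -4.59 ± 0.28.

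Of the 15143 genes, 1722 were higher and 1805 lower by limma at an adjusted p under 0.05, and 11616 did not pass. At least 2-fold differences made up 1015 of the higher and 1053 of the lower calls, and 50 and 72 exceeded 8-fold. The other genes with the largest positive means were ugt-22 at 3.93 ± 0.50, bcf-1 at 3.90 ± 1.06, the cuticle collagen gene col-161 at 3.84 ± 1.14 and abu-15 at 3.83 ± 1.44. The uterine lumen genes ule-3, ule-4 and ule-5 were at -4.94 ± 0.56, -4.88 ± 0.58 and -4.13 ± 0.48, stha-3 at -4.85 ± 0.50 and the collagen gene col-36 at -4.52 ± 0.22. The adjusted p-values of these 16 genes lay between 6.26e-06 and 0.000187. In prep 2, ule-3 and ule-4 had the same value, -5.45, the lowest on that array (-5.51 before centring). Low ratios are stored in whole thousandths and fall in coarse steps, so means and SDs of the lowest genes are approximate. Without prep 2 the counts were 767 higher and 1007 lower. With a one-sample test that shares no spread between genes, 0 genes passed, while 3274 had an unadjusted p under 0.05 there and 5390 with limma.

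**Figure D1:**
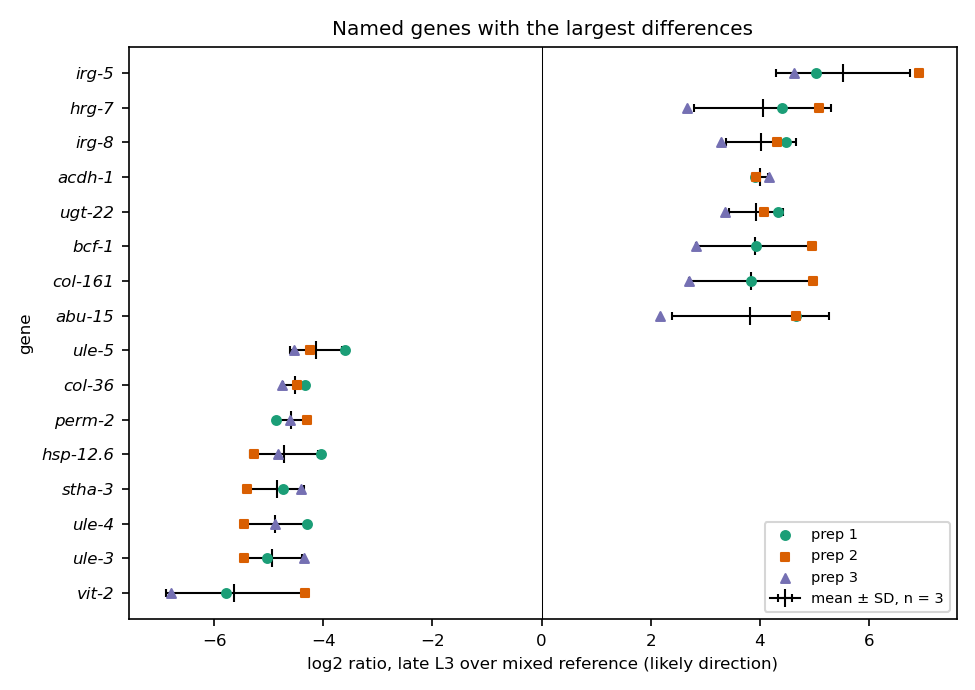
Log2 ratio of late L3 over reference (likely direction, centred on the array median) of the 16 named genes with the largest changes. Points are the 3 preps, with the mean and SD for each gene. irg-5 has the highest mean, 5.53, and vit-2 the lowest, -5.63.

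The direction of the ratio was set against vitellogenin and oocyte genes, which are adult transcripts. vit-2 was far below the median in each prep, at -5.78, -4.33 and -6.79. In contrast, vit-5 at 0.27 ± 0.24 (adjusted p = 0.400) and vit-6 at -0.01 ± 0.43 (adjusted p = 0.973) were not distinguishable from it. The list of 3 measured vitellogenin genes therefore had 1 lower member, also when adjusted over the list alone, with a median of -0.01 and a mean of -1.79, and was too short for a list test. Of 36 measured oocyte and eggshell genes, 30 were lower and 0 higher. The vitellogenins do not settle the direction. The oocyte and eggshell list had medians of -2.38, -2.12 and -2.08 in preps 1, 2 and 3. With the reverse direction, larvae would hold more of these adult transcripts than the mixed reference, so these values argue against it. The stages in the reference are not given, so late L3 over reference stays the likely direction.

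Of 30 genes of the major sperm protein, the cytoskeletal protein of nematode sperm, 29 were lower, with a median log2 ratio of -2.23. In prep 2, 5 of the 30 (16.7%) lay over 1 log2 unit above both other preps, against 3.24% of all genes. All genes include those with small ratios. Here and below, a list with large ratios can exceed that share for this reason alone. Among the 29 lower genes, msp-51 was at -3.94 ± 0.25 and msp-59 at -3.87 ± 1.12. Other spermatogenesis genes had 20 of 52 members lower and 0 higher, with gipc-2 at -2.45 ± 0.47, sss-1 at -2.44 ± 0.61 and msd-4 at -2.41 ± 0.22. The oocyte and eggshell list had a median of -2.21, with the eggshell proteoglycan genes cpg-3 at -3.95 ± 0.46 and cpg-1 at -3.70 ± 0.16 and the oocyte maturation gene oma-2 at -3.67 ± 0.71. Adjusted over the list alone, 29, 21 and 31 members were lower, and 0, 2 and 0 higher. Camera gave adjusted p-values of 5.28e-23, 9.15e-06 and 3.27e-22, and adjusted p = 0.277, 0.237 and 0.237 with an estimated correlation. Genes of the major sperm protein are near-identical copies, so single members are uncertain.

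Genes of germ line proliferation and meiosis went both ways. Of 52 measured, 7 were higher and 16 lower. The P granule helicase genes glh-1 and glh-2 were higher at 2.08 ± 0.42 and 1.77 ± 0.47, while syp-3, of the synaptonemal complex, and zim-1, a chromosome pairing protein, were lower at -1.63 ± 0.65 and -1.57 ± 0.48. DNA replication and cell cycle genes had 1 higher and 10 lower of 59, among them the cyclin B gene cyb-3 at -1.56 ± 0.06, the mitotic kinase gene cdk-1 at -1.45 ± 0.67 and the centromeric histone gene hcp-3 at -1.32 ± 0.58. Embryo genes had 1 higher and 9 lower of 55, with sdz-27 at -2.64 ± 0.66, sip-1 at -2.50 ± 0.12, pes-2.1 at -2.41 ± 0.44 and tbx-9 at -1.13 ± 0.19. Adjusted over the list alone, the germ line list had 7 higher and 18 lower members, the cell cycle list 1 and 10, and the embryo list 1 and 8. Medians were -0.32, -0.20 and -0.19, with camera adjusted p-values of 0.0291, 0.0187 and 0.0187, and adjusted p = 0.317, 0.571 and 0.317 with an estimated correlation. The germ line call was lost without prep 1 (adjusted p = 0.137) and without prep 3 (0.0631), the cell cycle call without prep 1 (0.239) and the embryo call without prep 3 (0.0612). The germ line call also ended with values on at least 2 arrays (0.0851), with each probe tested alone (0.0538) and without the 10% of genes with the largest spread (0.140), and the cell cycle call with the first (0.0749), the last (0.139) and fry (0.178).

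Cuticle collagens included members at both ends of the range. Of 151 measured, 63 were higher and 29 lower, with col-17 at 3.79 ± 0.68 and dpy-13, mutants of which are short and stout, at 3.77 ± 0.95, against col-36 at -4.52. Moulting and hedgehog-related genes had 25 higher and 12 lower of 120, with the cuticlin gene cut-2 at 3.79 ± 0.71, grl-7 at 2.70 ± 1.52 and grd-6 at 2.59 ± 0.35, and grl-3 lower at -2.79 ± 0.49. Prep 1 stood apart for many moulting genes: 23 of the 120 (19.2%) were over 1 log2 unit below both other preps there, against 3.53% of all genes, and list medians were 0.12, 0.69 and 0.26 in preps 1, 2 and 3. In prep 3, 7 of the 120 (5.83%) lay as far below both others, against 1.16% of all genes. The gene noah-1, chosen after its values were seen, was at -0.35, 2.42 and 2.39, and nas-37, chosen likewise, at -1.02, 2.07 and 1.34. Of the 151 collagens, 24 (15.9%) lay as far below both others in prep 3 and 13 (8.61%) in prep 1, against 1.16% and 3.53% of all genes. Values of all probes were also less spread in prep 3. Their median absolute deviation, scaled to match an SD, was 0.39 there, against 0.69 and 0.77 in preps 1 and 2. The prep 3 share therefore need not be particular to collagens. Adjusted over the list alone, 66 and 30 collagens and 38 and 12 moulting genes were higher and lower. Medians were 0.52 and 0.32, with camera adjusted p-values of 0.000131 and 0.00228, and adjusted p = 0.411 and 0.492 with an estimated correlation. Without the 10% of genes with the largest spread the collagen shift turned to the lower side (adjusted p = 0.871) and the moulting call ended (0.140), and fry gave 0.136 and 0.194. Among the collagens furthest from the median, higher members often had larger SDs than lower ones, as 1.14 for col-161 against 0.22 for col-36. Leaving out genes by spread can therefore remove more higher than lower collagens. Collagen genes share sequence, so single members can cross-hybridise. The heterochronic list, which times larval fates, had 4 of 11 members higher and 1 lower, with the same counts adjusted over the list alone, and did not pass (median 0.32, adjusted p = 0.209). The period homologue lin-42 was at 1.08 ± 0.36, but its adjusted p was 0.0585 without prep 2.

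Of 41 measured muscle genes, 24 were higher, 1 was lower and 16 did not pass, with a median of 1.11. List medians were 0.88, 1.47 and 0.77 in preps 1, 2 and 3, and 5 of the 41 lay over 1 log2 unit above both other preps in prep 2, against 3.24% of all genes. The myosin heavy chain gene myo-3 was at 2.76 ± 1.12, the perlecan gene unc-52 at 2.63 ± 0.53, the troponin T gene mup-2 at 2.47 ± 0.28 and the alpha-actinin gene atn-1 at 2.26 ± 0.54. Adjusted over the list alone, 27 were higher and 1 lower. Camera gave an adjusted p of 1.33e-11, and adjusted p = 0.338 with an estimated correlation. The somatic gonad list had 7 higher and 5 lower of 24 (7 and 6 adjusted over the list alone), and did not pass (median 0.25, adjusted p = 0.276). Its higher members included genes of basement membrane proteins, the type IV collagen gene emb-9 at 2.99 ± 0.62, the laminin gene epi-1 at 2.77 ± 0.67 and the hemicentin gene him-4 at 1.85 ± 0.74, and the innexin gene inx-14 was lower at -2.05 ± 0.21. Vulva and inductive signalling genes had 3 higher and 4 lower of 38 (2 and 4 adjusted over the list alone). The Notch receptor gene lin-12 was at 1.27 ± 0.57 and the EGF gene lin-3 at -0.99 ± 0.07. The vulva list did not pass (adjusted p = 0.837), and its median of 0.0011 differed in sign from its mean of -0.04 and from camera, which placed it on the lower side.

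Intestine and digestion genes had 21 higher and 12 lower of 71 (26 and 14 adjusted over the list alone), and the list did not pass (median 0.13, adjusted p = 0.135). In prep 2, 8 of the 71 (11.3%) lay over 1 log2 unit above both other preps, against 3.24% of all genes. The cathepsin B gene cpr-5 was at 3.46 ± 0.36 and the P-glycoprotein gene pgp-1 at 3.01 ± 1.72, while the metallothionein gene mtl-1 was at -3.17 ± 0.39 and cpr-2 at -2.54 ± 0.83. Nerve genes had 1 higher and 19 lower of 59 (1 and 20 adjusted over the list alone), 39 did not pass, and the median was -0.40. The flp neuropeptide family, with all its 22 measured genes in fixed lists, had 12 lower and 0 higher (median -0.76). Many of the nerve calls thus come from this family, and the shift need not hold for nerve genes in general. The neuropeptide-like nlp family, chosen after its values were seen, had 27 lower and 1 higher of 53 (median -0.72). Of these 53 genes, 9 were in fixed lists. In prep 1, 4 nerve genes (6.78%) lay over 1 log2 unit below both other preps, against 3.53% of all genes. Camera gave an adjusted p of 6.07e-05, and adjusted p = 0.237 with an estimated correlation. The members furthest down were tbh-1 at -3.20 ± 0.49 and tdc-1 at -2.82 ± 0.60, enzymes of octopamine and tyramine synthesis that are also expressed in gonadal sheath cells, and the neuropeptide genes flp-1 and flp-6 were at -1.60 ± 0.15 and -1.43 ± 0.72. Of 14 male genes, 0 passed the threshold in limma, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05, and the furthest from 0 were trf-1 at 0.47 ± 0.66 and cwp-3 at 0.45 ± 0.50. The male list did not pass (median 0.02, adjusted p = 0.843).

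Of 50 ribosomal protein genes 26 were higher, 0 lower and 24 did not pass (33 and 0 adjusted over the list alone), with a median of 0.80, and rps-9, rpl-3 and rpl-4 were at 1.75 ± 0.51, 1.62 ± 0.50 and 1.61 ± 0.31. Of 38 genes of oxidative phosphorylation 18 were higher, 0 lower and 20 did not pass (23 and 0 adjusted over the list alone), with a median of 0.67, and the complex III gene ucr-2.2 and the ATP synthase genes atp-2 and atp-1 were at 2.21 ± 0.33, 1.89 ± 0.53 and 1.88 ± 0.33. Camera gave adjusted p-values of 4.54e-12 and 3.11e-07, and adjusted p = 0.237 and 0.338 with an estimated correlation. In prep 2, 4 ribosomal protein genes (8%) and 3 of oxidative phosphorylation (7.89%) lay over 1 log2 unit above both other preps, against 3.24% of all genes, and 4 ribosomal protein genes lay as far below both in prep 1, against 3.53%. Histone genes had 4 higher and 4 lower of 63 (3 and 4 adjusted over the list alone) and the list did not pass (median 0.17, adjusted p = 0.555). In prep 2, 5 (7.94%) lay as far above both others. The linker histone gene hil-7 was at -1.15 ± 0.19. Core histone genes are near-identical copies, and single members are uncertain. Heat shock and stress genes had 7 higher and 5 lower of 26 (9 and 5 adjusted over the list alone). The ER chaperone gene hsp-3 and the HSP70 gene hsp-1 were higher at 2.41 ± 0.33 and 1.31 ± 0.31, and hsp-12.3 was lower at -2.62 ± 0.63. The heat shock list did not pass (median 0.44, adjusted p = 0.135), while fry, which tests the list against 0, gave 0.0206.

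Fatty acid synthesis and lipid binding genes had 12 higher and 9 lower of 44 (14 and 11 adjusted over the list alone). The delta-6 desaturase gene fat-3 was at -3.66 ± 0.33 and the acyl-CoA synthetase gene acs-2 at -3.19 ± 0.28, against the lipid-binding protein gene lbp-7 at 2.31 ± 0.35. The list did not pass (adjusted p = 0.921), with a median of -0.01 and a mean of -0.03 where camera placed it on the higher side. Innate immunity and antimicrobial peptide genes had 6 higher and 18 lower of 43 (7 and 18 adjusted over the list alone), with irg-5, irg-8, irg-7 at 3.49 ± 1.15 and irg-4 at 3.33 ± 0.29 among the higher. In prep 2, 4 of the 43 (9.3%) lay over 1 log2 unit above both other preps, against 3.24% of all genes, and in prep 3, 3 (6.98%) lay as far below both, against 1.16%. The immunity list did not pass (median -0.38, adjusted p = 0.0822), but did with array weights (0.0431) and after the identifier trend was removed (0.0200). Insulin and TGF-beta genes had 2 higher and 5 lower of 45 (2 and 4 adjusted over the list alone; median -0.18, adjusted p = 0.209), with the insulin-like gene ins-7 at -1.55 ± 0.53. Wnt and Hox genes had 2 higher and 3 lower of 19, the same adjusted over the list alone, with the Wnt gene mom-2 at -1.85 ± 0.56. The Wnt list did not pass (median -0.13, adjusted p = 0.555), while fry gave 0.0206.

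**Figure D2:**
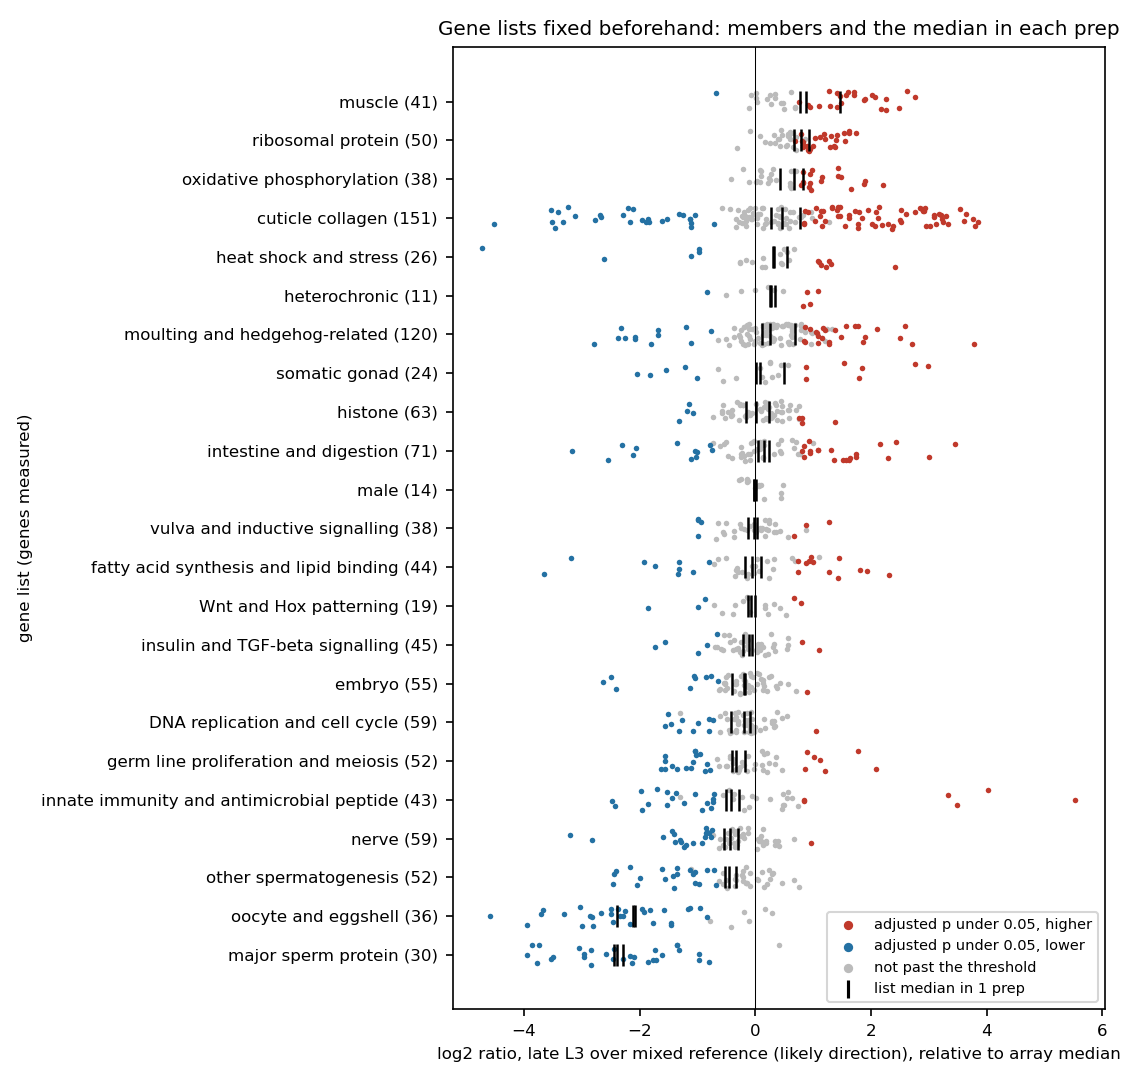
Log2 ratio of late L3 over reference (likely direction, centred on the array median) of the members of the 23 tested gene lists. Each dot is the mean of a gene over the 3 preps, coloured by whether it passed the threshold, and black ticks are the list medians in each prep. The major sperm protein and oocyte lists have medians of -2.23 and -2.21, and the muscle list 1.11.

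In all, camera called 12 of the 23 lists, 5 higher and 7 lower. With an estimated correlation, 0 lists passed, and 4 had an unadjusted p under 0.05, namely oocyte and eggshell (0.0145), other spermatogenesis (0.0285), nerve (0.0328) and ribosomal protein (0.0413). That test has 2 residual degrees of freedom here. Its p was larger even where the estimated correlation lay below the preset 0.01, as for other spermatogenesis (-0.0096) and germ line (-0.0118). The loss of those calls is not due to correlation. Some other called lists had estimates above the preset, such as major sperm protein (0.272), muscle (0.259) and oxidative phosphorylation (0.134). There, correlation may add to the loss, and the preset p-values may be too small. fry called 11.

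X-linked genes were more often higher and less often lower than the pooled autosomal genes. Of 2265 genes on the X chromosome, 331 (14.6%) were higher and 222 (9.8%) lower, against 1384 (10.8%) higher and 1581 lower of 12805 autosomal genes. Examples on the X chromosome are mup-2, ucr-2.2 and hsp-3 among the higher genes and vit-2, stha-3 and tbh-1 among the lower. The odds ratio of higher calls was 1.41 (95% interval 1.24 to 1.61, Fisher's exact p = 3.29e-07) and that of lower calls 0.771 (0.662 to 0.896, p = 0.000502). The autosomes differed among themselves: on chromosome III 13% were higher and 9.73% lower, close to the X chromosome, while 14.2% were lower on chromosome I and 14.7% on IV. Genes are not independent replicates. The difference of medians between X-linked and autosomal genes was 0.12 in prep 1, -0.09 in prep 2 and 0.06 in prep 3, so prep 2 went the other way. Without prep 1 the odds ratio of lower calls was 0.922 (Fisher's exact p = 0.317). With 1 prep left out, the odds ratio of higher calls was 1.27 to 1.31, below the 1.41 with all 3. The measured major sperm protein, other spermatogenesis and oocyte and eggshell genes were all autosomal. Their lower calls add to the autosomal share, by an amount not given here.

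Ratios were correlated between the 3 preps. Across genes, Pearson's r was 0.712 between preps 1 and 2, 0.721 between 1 and 3 and 0.779 between 2 and 3, and Spearman's rho was 0.606, 0.629 and 0.665. Genes are not independent replicates, and no p-value is given. A single sign on all arrays was seen for 8477 genes (56%), against 25% for independent signs, a share that the common reference on every array raises by an amount not estimated here. The median SD between preps was 0.34. Spread differed between named genes, from 0.06 for cyb-3 to 1.72 for pgp-1. Ratios were smaller in prep 3: for 833 genes over 2-fold higher in both other preps its ratio was 0.636 of their mean on the log2 scale (median), and for 862 genes over 2-fold lower it was 0.787. Genes picked in this way tend to be smaller in the prep left out, and the same shares were 0.86 and 0.978 for prep 1 and 1.23 and 1.03 for prep 2.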

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

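Probes that could not be assigned to a single gene were left out of all comparisons, and many of them carried a signal. Of 4196 such probes with values on all arrays, 626 (14.9%) passed the threshold in limma, 368 higher and 258 lower, with means from -6.62 to 4.16 on the log2 scale. Among probes with 1 gene, 3451 of 15576 (22.2%) passed. No explanation was tested.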

How the results depend on the processing

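No paired analysis was possible because there was 1 group. Turning the signs of 1 array at a time gave at most 0 genes past the threshold in limma (32 to 133 at an unadjusted p under 0.05), against 3527 with the real signs. The real signs were 1 of 4 arrangements, too few for a share under 0.05. Of the 1624 values recomputed under alternatives, 1552 kept their direction and side of the threshold or stayed close. No called gene changed sign under any scaling. The removal of the identifier trend was chosen after seeing the data.

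Counts of higher and lower genes moved to 0 and 0 in the one-sample test (3274 genes at an unadjusted p under 0.05), to 1015 and 1053 with a 2-fold minimum and to 896 and 1006 at an adjusted p under 0.01, both because the criteria are stricter. Without 1 prep they ranged from 767 to 1756 and from 1007 to 1547, the lowest both without prep 2, and the cause was not tested. With every sign turned they were 1805 and 1722 by construction.

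Adjusted p-values of list shifts that changed side were as follows, and the cause was not tested. With values on at least 2 arrays they were 0.0851 for germ line and 0.0749 for cell cycle, and 0.800 for fatty acid on the opposite side. Each probe alone gave 0.0538 for germ line. Without the genes of largest spread they were 0.140 for germ line, 0.139 for cell cycle and 0.140 for moulting, with collagen (0.871) and fatty acid (0.771) on the opposite side. Innate immunity passed with array weights (0.0431) and without the trend (0.0200). An estimated correlation, with 2 residual degrees of freedom by construction, left 0 lists, at 0.237 for oocyte, other sperm, nerve and ribosomal protein, 0.277 for major sperm protein, 0.317 for germ line and embryo, 0.338 for muscle and oxidative phosphorylation, 0.411 for collagen, 0.492 for moulting and 0.571 for cell cycle. fry gave 0.178 for cell cycle, 0.136 for collagen, 0.194 for moulting, 0.231 for fatty acid on the opposite side, and 0.0206 for both heat shock and Wnt. Leaving out 1 prep gave 0.0296 to 0.137 for germ line, 0.00742 to 0.239 for cell cycle, 0.0243 to 0.0612 for embryo, 0.251 to 0.963 for histone (opposite side without prep 2) and 0.947 to 0.983 for fatty acid (opposite side without prep 3).

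The X odds ratio of lower calls ranged from 0.687 to 0.922 without 1 prep, and that of higher calls from 1.27 to 1.31. Near 0, vit-6 turned to 0.0269 with equal scale, 0.0281 with quantile normalization, 0.0592 with array weights and 0.0906 without the trend, and ranged from -0.19 to 0.23 without 1 prep, and vit-5 turned to -0.0786 without the trend. Of 101 named genes, 12 lost their call without prep 2, 2 without prep 1, 4 without prep 3, 1 with equal scale and 2 without the trend. Named genes were not run with each probe alone, and lists, X and named genes were not run with turned signs, which mirror them. Spot signal over background was not used here, so limits for dim spots are unknown.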

Other observations

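The tests of gene families, of the removed identifier trend and of neighbours over 500 identifiers apart were chosen after the data were seen. Among 190 families of genes that share the letters of their symbol, camera called 28, of which 15 held no member of a fixed list. With an estimated correlation 0 families passed, and each of the 15 had an adjusted p of 0.747, in a test with 2 residual degrees of freedom that says little about them. In the abu family 12 of 13 genes were higher, with a median log2 ratio of 2.65 (adjusted p = 7.05e-09), and adjusted p = 0.747 with an estimated correlation. Its leading genes abu-15 at 3.83 ± 1.44 and abu-8 at 3.33 ± 1.44 were lower in prep 3, at 2.16 and 1.67, than in preps 1 and 2, at 4.67 and 4.66 for abu-15 and 4.20 and 4.11 for abu-8. Across all genes over 2-fold higher in preps 1 and 2, ratios in prep 3 were also smaller, at a median of 0.636 of their mean. Glucuronosyltransferase genes (ugt) had 26 higher and 3 lower of 63 (median 0.50, adjusted p = 3.29e-06, and adjusted p = 0.747 with an estimated correlation), with ugt-8 at 3.11 ± 0.78 and ugt-16 at 3.06 ± 0.61. Heme-responsive genes (hrg) had 5 of 9 higher, with hrg-11.2 at 2.95 ± 0.76, and acyl-CoA dehydrogenases (acdh) 5 of 11. Translation initiation factors (eif) had 9 of 19 higher, and mitochondrial ribosomal proteins 8 of 20 (mrps, with 1 lower) and 7 of 25 (mrpl).

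Transthyretin-related genes (ttr) had 1 higher and 21 lower of 46 (median -0.65, adjusted p = 2.11e-06, and adjusted p = 0.747 with an estimated correlation), with ttr-50 at -3.02 ± 0.32. The pals family had 7 lower and 1 higher of 24 (median -0.56, adjusted p = 0.00150, and adjusted p = 0.747 with an estimated correlation), led by pals-39 at -3.37 ± 0.70, and the Skp1-related genes (skr) 7 lower of 16, led by skr-9 at -2.26 ± 0.65. The adult collagen gene col-19, chosen after its values were seen, was at -2.66 ± 0.33. The medians of the 15 kept their sign in all 7 settings of scaling, left-out prep and trend. Members of a family can cross-hybridise.

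Deviations of single arrays from the mean followed the order of probe identifiers, with a correlation between successive probes of 0.377, 0.265 and 0.297 in preps 1, 2 and 3. After a running median was removed the counts were 1737 higher and 1865 lower, and a share of 0.845 of the called genes stayed called with the same sign. This lies between the bounds set beforehand, under 0.5 if the trend made the calls and at least 0.9 if not, so how far it contributes cannot be told apart from other noise. The correlation of successive deviations was still 0.172, 0.185 and 0.13 after removal. For the mean of the preps, on which the calls rest, the correlation between successive probes was 0.121 before and 0.0552 after removal. No biological explanation was tested.

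Neighbouring genes on a chromosome had similar ratios, with a correlation across 15064 pairs of 0.167, against -0.024 to 0.0423 in 1000 shuffled orders. It was 0.213 for starts within 3 kb, 0.142 at 3 to 10 kb and 0.0728 at 10 to 30 kb, the last inside its shuffled range of -0.0628 to 0.0756. Probes close together in the order of identifiers may add to this, but pairs over 500 identifiers apart still gave 0.157. The position of probes on the array was not used here, so nearness on the array was not tested. Copies of a gene that cross-hybridise may add to it too, and pairs of the same symbol family gave 0.462, which was not separated from shared regulation, but pairs of different families still gave 0.121, above the shuffled range of -0.0349 to 0.0571. The values 0.157 and 0.121 argue against close identifiers and copies within a named family as the whole cause. Nearness on the array, operons, shared regulation and unnamed paralogs stay open and were not tested.

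The genes hsp-12.6, acs-2, mtl-1 and cut-1 (-2.37 ± 0.41) were far below the median, a set chosen after its values were seen. All are known to be raised in fasting or in dauer larvae, so a candidate explanation is that the mixed reference held such animals. In a list of other fasting and dauer genes, written before its test, 10 of 21 measured were lower and 3 higher, with a median of -0.605 (95% bootstrap interval -0.917 to 0.124). The median and camera (p = 0.0129) met the condition set beforehand, but the interval, a requirement added after it was seen, includes 0, the p with an estimated correlation was 0.236, and lipl-5, pck-1 and lipl-3 were higher at 2.22, 2.18 and 0.85, so the hypothesis stays open. After removal of the identifier trend the median of the 4 genes was -3.2. A running median follows many successive probes and takes little from single genes this far below the array median. The test could therefore hardly have come out otherwise, and no conclusion on the trend as a cause is drawn from it.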
